A study of Mus musculus with 12 samples.

How the data were processed

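RNA of 12 samples was measured on Agilent mouse arrays whose annotation gives probe positions on mm9. Each array carried a sample labelled with Cy5 and a common reference of mESC RNA labelled with Cy3, from 100 ng of RNA per the labels, with 0 dye swaps. Replicates 1, 2 and 3 of each group lay on slides 1, 2 and 3, so the replicate number is also the slide, and the position on the slide follows the group. Slide 2 was scanned on another day and read with Agilent Feature Extraction 10.5.1.1, and slides 1 and 3 with 10.7.3.1.

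The scanner files hold the mean signal of each spot and the median of its local background, both as intensity in each channel per the file headers, before background subtraction and dye normalization. They also hold a log ratio in log10 of Cy5 over Cy3 processed signals, per the file headers, which the software had background-subtracted with spatial detrending and dye-normalized with linear and LOWESS steps. The deposited table of values is in log2, and the labels do not say how it was made. Set against the scanner files, its values equalled the scanner's log ratio turned to log2 and averaged over the spots of a probe, to 0.001 for 99.4 to 99.5% of the probes of an array, with 175 missing values.

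The main values were computed from the mean signals in R 4.3.3 with limma 3.58.1, and the files were read with data.table (version 1.17.8). Background was corrected by normexp with an offset of 50, each array was normalized by loess, and the log2 ratio of Cy5 to Cy3 was taken with no normalization between arrays. Each array had 44397 spots, of which 1377 control spots and the 128 to 298 spots per array that the software marked as non-uniform or as outliers were left out, and spots of a probe were averaged, which left 39429 probes. Genes were named from the accessions and symbols in the files through the RefSeq table: 26581 probes matched by their accession, 100 by another accession, 2535 by symbol and 474 by a synonym, and 9739 had no name and were tested under the probe's own. A probe was tested between groups if Cy5 was well above background on all 3 arrays of at least 1 group, and against mESC also if Cy3 was so on all 12 arrays. Cy5 was well above background on 25605 to 29076 of these probes per array and Cy3 on 23424 to 25687. The probe with the highest mean intensity over all arrays stood for a gene. This gave 22319 genes between groups, 16911 of them with a symbol, and 22450 against mESC, 17004 with a symbol.

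All 12 arrays entered 1 linear model on the 4 group means with moderated tests by eBayes, two-sided, adjusted by Benjamini and Hochberg, with a threshold of 0.05 on the adjusted p. The comparisons were enriched against control cells at each step, step 5 against step 4 in each kind of cell, the difference between the enrichment effects, and each group against mESC. SE values are those of the moderated model, and the slide values are differences between arrays of a slide. The labels name no pairing. The deviations of arrays from their group means correlated across genes between arrays of the same number at 0.463 to 0.747 for control cells of both steps and 0.341 to 0.413 for enriched cells of both steps. Between control and enriched cells these correlations were 0.13 to 0.643 at step 4 and 0.188 to 0.362 at step 5. They were 0.251 to 0.334 for step 4 control with step 5 enriched cells and -0.133 to 0.227 for step 4 enriched with step 5 control cells. The replicate number as a block was therefore tried as an alternative and is printed beside a result where it changes a call or moves a count by more than 1.5 times.

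In all, 32 gene lists were written before the data were examined, and 31 with at least 5 tested genes were tested with camera at a preset correlation of 0.01 on 22226 genes, after 93 with a missing value were left out. They covered the sort antigen and its sialyltransferases, neurogenic transcription factors, the immature neuronal cytoskeleton, synapses, GABAergic, glutamatergic, dopaminergic and motor neurons, radial glia, the Notch pathway, astrocytes, the oligodendrocyte lineage, pluripotency, the cell cycle, mesenchyme, muscle, endothelium, blood, endoderm and epithelium, neural crest, forebrain, midbrain and hindbrain, Hox genes, migration and axon guidance, immediate early genes, retinoid response, cholesterol, oxidative stress, hypoxia, FGF and MAPK feedback and interferon. The list for serotonin neurons had under 5 tested genes and was not tested. Of the 590 genes in the lists 28 stand in more than 1 list, such as Dlx1 and Dlx2 in the GABAergic and forebrain lists, and Col6a3 and Hspa1b had no probe. Camera with a correlation estimated from the data and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it, and members were counted as past the test over all genes and adjusted over the list alone.

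The genes named were set by a rule written before the data were examined. It takes 12 genes in every comparison (Ncam1, St8sia2, St8sia4, Dcx, Tubb3, Map2, Nes, Sox2, Pax6, Gfap, Pou5f1 and Mki67), the 8 largest rises and 8 largest falls past the test with the same sign on all 3 slides, and up to 4 members of each list with the smallest adjusted p, and against mESC the first and last of these. A gene named by the rule in 1 comparison is also given in others where its value belongs to the comparison.

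The steps were tested on simulated data of the same size. Of 50 genes changed by each amount in a simulated enrichment at step 4, 9 were recovered at a log2 change of 0.5, 28 at 1, 44 at 2 and 47 at 3, with 5 unchanged genes past the test among 22226. For simulated steps in control cells 7, 28, 43 and 46 were recovered, with 4 unchanged genes past the test. In both simulations a list raised by 0.5 passed and 0 of 30 unchanged lists did. The simulated noise was drawn independently for each gene, so these runs do not test lists whose genes vary together.

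The alternatives were no background subtraction, the scanner's own log ratio, the deposited table, median centring in place of loess, Aquantile after loess, Cy5 alone, no filter on dim probes or one on all arrays, the mean over the probes of a gene, an intensity trend in eBayes, the replicate block, only the arrays of the groups compared, and leaving out each array in turn. Cy5 alone was taken after loess and Aquantile, so it was still scaled with the Cy3 reference. Aquantile after loess leaves every ratio as it was, so that run could not change a call. The deposited table nearly repeats the scanner's log ratio. Counts of alternatives given below include both, so they are not counts of independent checks. Leaving out whole slides, the block together with an estimated correlation and the lists with each array left out were added after the data had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.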

Results

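Gene expression was measured in cells grown from C57BL/6 mouse embryonic stem cells (mESC) that carry eGFP under an actin promoter, at 2 steps of a neural differentiation protocol. At step 4 the neural precursors had expanded for 5 days with bFGF at 10 ng/ml, and at step 5 they had differentiated for 7 days with ascorbic acid at 200 µM and without bFGF. Cells enriched with magnetic beads for PSA-NCAM, the polysialylated form of the neural cell adhesion molecule, were set against unsorted control cells at each step. The protocol had sorted precursors plated again and differentiated further, and the labels leave open whether the enriched cells of step 5 were sorted before or after those 7 days. The 4 groups had 3 biological replicates each, which gave 12 arrays, and each array set a Cy5-labelled sample against the same Cy3-labelled mESC RNA. All values are therefore log2 ratios to mESC or differences between such ratios, and the number of arrays limits their precision. Each of the 3 slides held 1 array of each group. Across genes, which are not independent replicates, arrays of a group correlated at r = 0.90 to 0.96 for step 4 enriched cells and 0.94 to 0.96 for step 5 enriched cells, against 0.74 to 0.85 and 0.66 to 0.92 for the control cells. The control arrays of slide 2 stood apart, with a mean r of 0.762 to the other control arrays at step 4 and 0.71 at step 5, where those others reached 0.85 and 0.918 with each other.

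**Figure D1:**
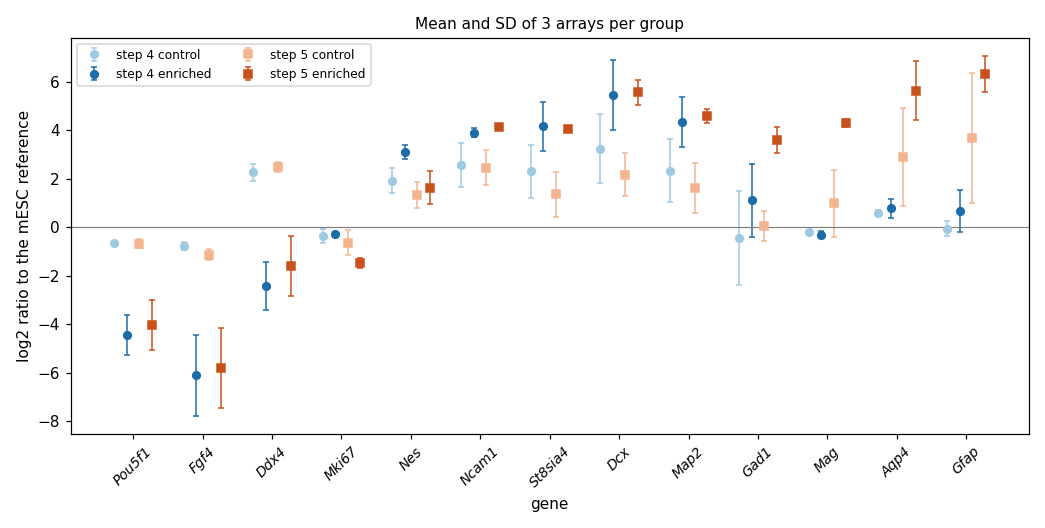
Log2 ratio to the mESC reference of 13 genes in the 4 groups, as the mean of 3 arrays with SD bars. Pou5f1 lay at -0.67 and -0.69 in control cells of steps 4 and 5 and at -4.45 and -4.04 in enriched cells.

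The first comparison asked which genes differed between PSA-NCAM-enriched and control cells among the neural precursors of step 4. Of the pluripotency genes 25 of 27 were lower in enriched cells, and 11 of 30 neural stem and radial glia genes, 18 of 32 genes of migration and axon guidance and 10 of 18 cholesterol genes were higher. Camera placed these 4 lists apart, but each had adjusted p = 0.616 with an estimated correlation. Pou5f1, which encodes the pluripotency factor Oct4, fell by 3.78 on the log2 scale (SE 0.48, n = 3 per group, adjusted p = 0.000548), a 13.7-fold difference, with -4.27, -2.79 and -4.28 on slides 1, 2 and 3. Ncam1, which encodes the carrier of polysialic acid, rose 2.54-fold (log2 1.34, SE 0.43, adjusted p = 0.0372). The enzymes that build polysialic acid rose too, St8sia2 2.59-fold (log2 1.37, SE 0.27, adjusted p = 0.00473) and St8sia4 3.62-fold (log2 1.86, SE 0.63, adjusted p = 0.0467), and all 3 genes were higher on all 3 slides. Of 27 alternatives to the processing, including arrays left out, St8sia4 did not pass under 17, Ncam1 under 14 and the neural stem cell marker Nes under 13, while St8sia2 did not pass under 3 and Pou5f1 passed under all. Without step 4 control replicate 2 the value of Ncam1 was 0.86 (adjusted p = 0.125) and that of St8sia4 1.38 (adjusted p = 0.167). Leaving out any of 7 single arrays ended the call of Ncam1, and 8 that of St8sia4.

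By limma, 6950 of 22319 tested genes (31.1%) differed at step 4, of which 3340 rose and 3610 fell, with 1162 and 1378 of them changed at least 2-fold. The balance depends on the scaling, and with each array centred on its median 4789 rose and 2574 fell. The largest falls were those of Fgf4, a growth factor gene of stem cells (40.4-fold), Arl14epl (39.7-fold), the meiotic cohesin gene Smc1b (36.3-fold) and Nlrp4f (32.3-fold). They were followed by the germline genes Mael (29.5-fold) and Ddx4 (25.9-fold), Zbtb32 (27.6-fold) and Dnmt3l, a cofactor of DNA methylation (25.6-fold), each on 3 of 3 slides. Mael and Ddx4 lay above the mESC level in step 4 control cells, at 2.22 and 2.26, and below it in enriched cells, at -2.66 and -2.44. The largest rises were those of Aldoc (8.38-fold, adjusted p = 0.0219), the desaturase gene Scd2 (7.74-fold, adjusted p = 0.000226), Lrrn3 (6.75-fold) and Fgfbp3 (6.72-fold). Next came the tubulin gene Tuba1a (6.5-fold), Pik3r3 (6.39-fold), the cholesterol exporter gene Abca1 (6.07-fold) and Il18 (5.99-fold), again on 3 of 3 slides. Lrrn3 did not pass under 10 of 27 alternatives. Without 1 array the count was 4341 (step 4 control replicate 2), 4579 (step 4 enriched replicate 2) or 4432 (step 4 enriched replicate 3).

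Markers of neural stem cells and neurons did not all pass the test at step 4. Nes, the nestin gene, rose 2.25-fold (SE 0.39 on the log2 scale, adjusted p = 0.0419, 3 of 3 slides), and without step 4 control replicate 2 Nes had the value 0.92 (adjusted p = 0.15). Dcx had a log2 difference of 2.2 (SE 0.82, adjusted p = 0.0652, 0.0329 with slide as a block). Map2 had one of 2.0 (SE 0.71, adjusted p = 0.0539, 0.0258 with the block) and Pax6 of 0.69 (SE 0.25, adjusted p = 0.0604, 0.0454 with the block). Tubb3 had a difference of 1.92 (SE 0.94, adjusted p = 0.146, higher on 2 of 3 slides), and without step 4 enriched replicate 1 Tubb3 rose by 2.83 (adjusted p = 0.037). Gfap, the marker of astrocytes, had one of 0.72 (adjusted p = 0.641), Sox2 one of 0.09 (adjusted p = 0.839) and the proliferation marker Mki67 one of 0.06 (adjusted p = 0.868), each higher on 2 of 3 slides. The neuronal list had a median log2 ratio to mESC of 0.89 in step 4 enriched replicate 1 against 2.61 and 2.76 in replicates 2 and 3, and of 0.92, 0.09 and 1.78 in the control replicates.

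Of 31 gene lists tested at step 4, camera placed 12 higher and 5 lower, and 0 of them with an estimated correlation, while fry called 11. Pluripotency genes had a median log2 change of -3.29 (camera adjusted p = 1.13e-14, slide medians -3.96, -2.43 and -3.24), and 25 of 27 fell, as did 25 adjusted over the list alone. Their adjusted p = 0.616 with an estimated correlation. Dppa4 fell by 3.42 (SE 0.26), Tcl1 by 3.54 (SE 0.33), Esrrb by 2.0 (SE 0.15) and Gdf3 by 1.80 (SE 0.17) on the log2 scale. Cell cycle genes had a median of -0.78 (camera adjusted p = 3.37e-08, 3 of 3 slides), and 22 of 32 fell, as did 22 adjusted over the list alone. Their adjusted p was also 0.616 with an estimated correlation. Bub1 fell by 1.48 (SE 0.25), Tpx2 by 0.91, Gins2 by 0.80 and Kif11 by 0.70.

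Neural stem and radial glia genes stood higher at step 4, with a median of 1.16 (camera adjusted p = 1.65e-05), and 11 of 30 rose, or 17 adjusted over the list alone. This list had adjusted p = 0.616 with an estimated correlation. Cdh2 (2.05, SE 0.46), Sox1 (1.67, SE 0.38), Vim (1.66, SE 0.33) and Msi2 (1.32, SE 0.16) were among those that rose. Genes of neuronal migration and axon guidance had a median of 1.05 (camera adjusted p = 2.44e-06), and 18 of 32 rose while 2 fell, or 22 and 2 adjusted over the list alone. Here adjusted p = 0.616 with an estimated correlation. The adhesion gene Nrcam rose by 2.02 (SE 0.34) while Dab1 fell by 0.74 (SE 0.14). Cholesterol genes had a median of 0.80 (camera adjusted p = 4.44e-05), and 10 of 18 rose, or 11 adjusted over the list alone. Again adjusted p = 0.616 with an estimated correlation. Hmgcs1 (2.0, SE 0.49), Mvk (1.17) and Nsdhl (1.16) were among those that rose.

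Neuronal lists were also placed higher at step 4 by camera, with fewer members past the test and with adjusted p of 0.616 to 0.703 with an estimated correlation. Over all genes 3340 of 22319 rose, the share against which their members are to be read. Of the synaptic genes 10 of 37 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.81, camera adjusted p = 0.000344), with Syn2 at 2.02 and Rab3a at 2.04. Of the neurogenic transcription factors 8 of 26 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.99, camera adjusted p = 0.00127), and both lists had adjusted p = 0.644 with an estimated correlation. Sox4 rose by 1.83 and Dll1 by 1.22, while Eomes fell by 1.33. Of the genes of the immature neuronal cytoskeleton 6 of 30 rose and 2 fell, the same numbers as adjusted over the list alone, with a median of 1.23 and a camera adjusted p of 0.00214. For this list adjusted p = 0.703 with an estimated correlation. The slide medians were 0.16, 2.46 and 1.12. Mllt11 rose by 2.29 while Nefh fell by 2.42 and Prph by 1.13. Among the GABAergic genes 4 of 16 rose, as many as adjusted over the list alone (median 1.32, camera adjusted p = 0.0033). In the list of the sort antigen 3 of 5 genes rose, also 3 adjusted over the list alone (median 1.34, camera adjusted p = 0.0376), and the GABAergic and sort antigen lists both had adjusted p = 0.616 with an estimated correlation. The transcription factor genes Dlx1 (2.24, SE 0.60) and Dlx2 (2.39, SE 0.78) were among the GABAergic genes that rose, and Dlx2 did not pass without step 4 control replicate 2 (1.54, adjusted p = 0.141) and under 15 of 27 alternatives in all. Without step 4 enriched replicate 3 the synaptic median was 0.39 and the GABAergic one 0.77. The call of the sort antigen list ended without step 4 control replicate 2 (median 0.86, camera adjusted p = 0.0818), step 4 enriched replicate 2 (camera adjusted p = 0.0538) or step 4 enriched replicate 3 (camera adjusted p = 0.0953).

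Forebrain genes had a median of 1.62 at step 4 (camera adjusted p = 0.0207), and 7 of 13 rose while 2 fell, or 9 and 2 adjusted over the list alone. Midbrain and hindbrain genes had a median of 0.80 (camera adjusted p = 0.0267) with 6 of 15 higher, the number also found adjusted over the list alone, and both regional lists had adjusted p = 0.616 with an estimated correlation. Nkx2-1 rose by 1.82 (SE 0.36), Six6 by 1.96, Hoxa2 by 1.35 and Irx1 by 1.1, while Hesx1 fell by 1.37. Notch pathway genes had a median of 0.59 (5 of 17 rose and 1 fell, 6 and 1 adjusted over the list alone, camera adjusted p = 0.0267), with Notch2 at 1.2, and adjusted p = 0.616 with an estimated correlation. Endothelial genes had a median of -0.71 (4 of 11 fell, 5 adjusted over the list alone, camera adjusted p = 0.0236), with Egfl7 at -1.82 and Pecam1 at -1.34. For the endothelial list as well adjusted p = 0.616 with an estimated correlation. Of the genes of endoderm and epithelium 4 of 19 fell, against 3610 of 22319 over all genes. Adjusted over the list alone 4 fell too (median -0.82, camera adjusted p = 0.0236), with adjusted p = 0.703 with an estimated correlation. Mesenchymal genes had a median of 0.56 with 1 of 26 lower and 3 higher, below the share over all genes, 3340 of 22319. Adjusted over the list alone 1 was higher and 1 lower (camera adjusted p = 0.0492, 0.0549 with slide as a block). For this list too adjusted p = 0.703 with an estimated correlation. Cdh1 fell 11.1-fold (SE 0.67 on the log2 scale), Epcam 7.83-fold (SE 0.48) and Timp1 by 1.82, while Prrx1 rose by 1.22. Several of these calls ended with 1 array left out. Without step 4 control replicate 2 this held for midbrain and hindbrain (0.46, camera adjusted p = 0.0904), Notch (0.42, camera adjusted p = 0.0818), endoderm (-0.24, camera adjusted p = 0.163) and mesenchyme (0.47, camera adjusted p = 0.0818). The Notch call ended also without step 4 enriched replicate 2 (camera adjusted p = 0.0538). That of endoderm did so without step 4 enriched replicate 1 (-0.52, camera adjusted p = 0.0772) or 3 (-0.51, camera adjusted p = 0.0501), while its median was -1.34 without step 4 control replicate 1 and -1.41 without step 4 enriched replicate 2. That of mesenchyme did so without step 4 control replicate 3 (camera adjusted p = 0.121), step 4 enriched replicate 1 (camera adjusted p = 0.42) or 2 (camera adjusted p = 0.0538), or step 5 enriched replicate 1 (camera adjusted p = 0.0533). The endothelial median was -0.15 without step 4 control replicate 2 and -0.32 without step 4 enriched replicate 3.

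Further lists were not placed apart from other genes by camera at step 4. Their medians were 0.59 for glutamatergic genes (adjusted p = 0.141, 1 of 8 rose), 0.24 for motor and cholinergic genes (adjusted p = 0.199), 0.56 for astrocytes (adjusted p = 0.117, 1 of 16 rose) and 0.3 for the oligodendrocyte lineage (adjusted p = 0.502). They were -0.48 for smooth and cardiac muscle (adjusted p = 0.199, 3 of 17 fell and 1 rose), 0.18 for neural crest (adjusted p = 0.864), 0.2 for retinoid response (adjusted p = 0.528) and 0.52 for FGF and MAPK feedback (adjusted p = 0.41). The medians of dopaminergic (0), blood (-0.12), Hox (-0.02), immediate early (-0.05) and hypoxia genes (0.07) changed sign between scalings of the arrays. Interferon genes had a median of 0.32 (adjusted p = 0.502). Of the 15 genes of the oligodendrocyte lineage 0 passed limma over all genes, and 0 adjusted over the list alone, and Olig1 had the value 1.2 (SE 0.54, adjusted p = 0.12, 3 of 3 slides). Of these, astrocyte genes passed camera without step 5 control replicate 2 (adjusted p = 0.028), and glutamatergic (0.79, adjusted p = 0.0223) and muscle genes (-0.61, adjusted p = 0.0351) without step 4 enriched replicate 1.

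The second comparison asked which genes differed between enriched and control cells at the end of neuronal differentiation, step 5. Of the synaptic genes 27 of 37 rose, of the oligodendrocyte lineage 11 of 15 and of the astrocyte genes 11 of 16, while 26 of 27 pluripotency genes and 31 of 32 cell cycle genes fell. Camera placed these 5 lists apart, but the synaptic list had adjusted p = 0.554 with an estimated correlation and the other 4 had adjusted p = 0.523 with an estimated correlation. Dcx rose by 3.40 on the log2 scale (SE 0.82, n = 3 per group, adjusted p = 0.00832), with 2.29, 4.51 and 3.39 on slides 1, 2 and 3. Map2 rose 7.91-fold (log2 2.98, SE 0.71, adjusted p = 0.00756) and Tubb3 6.48-fold (log2 2.7, SE 0.94, adjusted p = 0.042), the latter not past the test under 13 of 27 alternatives. Without step 5 control replicate 2 Tubb3 had the value 1.93 (adjusted p = 0.144). Ncam1 rose 3.18-fold, St8sia4 6.45-fold, St8sia2 2.43-fold and St8sia3 by 1.93 on the log2 scale, all on 3 of 3 slides. Pou5f1 fell by 3.35 on the log2 scale (SE 0.48, adjusted p = 0.000544) and Mki67 by 0.83 (SE 0.24, adjusted p = 0.0175).

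By limma, 9027 of the 22319 genes (40.4%) differed at step 5, with 4528 higher and 4499 lower, and 2081 and 1803 of them changed at least 2-fold. With median centring 5959 were higher and 3059 lower. Among the largest rises were those of the proteoglycan gene Bcan (16.7-fold, SE 1.32 on the log2 scale, adjusted p = 0.0314) and the Notch target Hes5 (13.6-fold, adjusted p = 0.00883). Also among them were Gad1, which encodes an enzyme that makes GABA (11.7-fold, adjusted p = 0.0121), Zcchc12 (11.5-fold), Cldn11 (11.2-fold), Aldoc (11.2-fold) and Cntn1 (11-fold). The log2 value of Cldn11 was 3.49, and 2.29 without step 5 control replicate 2. The largest falls were those of Arl14epl (38.2-fold), the water channel gene Aqp3 (33.1-fold), Zbtb32 (25.5-fold), Fgf4 (25.3-fold), Rpl39l (23.5-fold), Rpl10l (23.2-fold), Mael (21.4-fold) and Fthl17d (21.2-fold). All 15 differences had the same sign on 3 of 3 slides, and Bcan did not pass under 9 of 27 alternatives, among them without step 5 control replicate 2 (2.65, adjusted p = 0.103). Gfap had a difference of 2.66 (SE 1.05, adjusted p = 0.0671, with 0.55, 6.15 and 1.27 on slides 1, 2 and 3). Pax6 had one of 0.41 (adjusted p = 0.221), Nes of 0.3 (adjusted p = 0.578) and Sox2 of 0.03 (adjusted p = 0.937).

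Camera placed 10 of the 31 lists higher and 4 lower at step 5, 0 of them with an estimated correlation, while fry called 17. Of the synaptic genes 27 of 37 rose and 2 fell, the same numbers as adjusted over the list alone (median 1.81, camera adjusted p = 4.28e-07, slide medians 1.81, 2.17 and 1.44). Here adjusted p = 0.554 with an estimated correlation. Cplx1 (2.39, SE 0.39), Vamp2 (1.84, SE 0.20) and Stx1a (1.0, SE 0.16) were among those that rose. Of the genes of the immature neuronal cytoskeleton 21 of 30 rose and 3 fell, or 24 and 3 adjusted over the list alone, with a median of 1.88 (camera adjusted p = 4.73e-05) and adjusted p = 0.623 with an estimated correlation. Of the GABAergic genes 10 of 16 rose and 1 fell, or 11 and 1 adjusted over the list alone (median 1.48, camera adjusted p = 0.00305). This list had adjusted p = 0.623 with an estimated correlation too. Among both, Crmp1 rose 6.38-fold, Stmn2 5.11-fold, Dlx1 6.5-fold and the neuropeptide gene Npy 3.07-fold, while Gata3 fell by 1.47 on the log2 scale. Neurogenic transcription factors had a median of 0.93 with 10 of 26 higher and 3 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.0382), including Scrt1 (2.52), Sox11 (2.52) and Eomes (-1.86). For this list adjusted p = 0.66 with an estimated correlation. Its call ended without step 5 control replicate 2 (0.76, camera adjusted p = 0.0988), step 5 control replicate 3 (camera adjusted p = 0.075) or step 5 enriched replicate 2 (camera adjusted p = 0.0771).

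Of the oligodendrocyte lineage 11 of 15 genes rose at step 5, also 11 adjusted over the list alone, with a median of 1.86 (camera adjusted p = 6.83e-06, 3 of 3 slides), and adjusted p = 0.523 with an estimated correlation. Of the astrocyte genes 11 of 16 rose, or 12 adjusted over the list alone, with a median of 1.71 (camera adjusted p = 0.000157, slide medians 1.14, 2.87 and 1.68, and 1.33 over all without step 5 control replicate 2). This list also had adjusted p = 0.523 with an estimated correlation. Cnp rose by 3.42 on the log2 scale (SE 0.47), the myelin gene Mag 9.85-fold (SE 0.51), Ugt8a, which encodes an enzyme of myelin lipid synthesis, 6.7-fold (SE 0.25), and the transcription factors Sox10 and Olig2 3.92-fold and 3.54-fold. The connexin gene Gjb6 rose 8.18-fold (SE 0.44), S100b 6.6-fold (log2 2.72, SE 0.65, and 1.74 without step 5 control replicate 2) and the glutamate transporter gene Slc1a2 3.31-fold (SE 0.38). Radial glia genes had a median of 1.13 with 15 of 30 higher, the number also found adjusted over the list alone (camera adjusted p = 0.00018), including Dbi (2.82), Sox1 (2.15) and Cdh2 (2.27). Here adjusted p = 0.613 with an estimated correlation.

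Cell cycle genes fell at step 5, 31 of 32 past the test and 32 adjusted over the list alone, with a median of -1.5 (camera adjusted p = 1.51e-15) and slide medians of -1.82, -0.91 and -1.98. Pluripotency genes fell in 26 of 27 cases, also 26 adjusted over the list alone, with a median of -3.05 (camera adjusted p = 2.35e-11), and both lists had adjusted p = 0.523 with an estimated correlation. Bub1 fell 5.78-fold (SE 0.25 on the log2 scale), Cdk1 3.55-fold (SE 0.19), Kif11 2.79-fold (SE 0.12), Tcl1 11.7-fold (SE 0.33) and Dppa4 8.69-fold (SE 0.26). Muscle genes had a median of -0.8 with 8 of 17 lower, as many as adjusted over the list alone (camera adjusted p = 0.015), among them Des (-1.68), Tpm2 (-1.75) and Myl4 (-1.91). For that list adjusted p = 0.623 with an estimated correlation. Of the genes of endoderm and epithelium 4 of 19 fell, close to the share over all genes, 4499 of 22319. Adjusted over the list alone 3 fell (median -1.22, camera adjusted p = 0.0155). Here adjusted p = 0.66 with an estimated correlation. Cdh1 fell 16-fold (SE 0.67 on the log2 scale), Epcam 7.66-fold and Afp 10.1-fold (SE 1.21, adjusted p = 0.0485), the last not past the test under 12 of 26 alternatives, among them without step 5 control replicate 2 (-2.04, adjusted p = 0.164). Both calls, of muscle (-0.59, camera adjusted p = 0.164) and of endoderm (-0.53, camera adjusted p = 0.168), ended without step 5 control replicate 2. Without step 5 enriched replicate 1 that of endoderm ended too (-0.75, camera adjusted p = 0.0863), and the muscle median was -0.53.

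Migration and axon guidance genes had a median of 1.21 at step 5, with 21 of 32 higher and 1 lower, or 24 and 1 adjusted over the list alone (camera adjusted p = 1.76e-06). In the list of the sort antigen 5 of 5 genes rose, also 5 adjusted over the list alone (median 1.67, camera adjusted p = 0.00502), and both lists had adjusted p = 0.523 with an estimated correlation. Nrcam (2.39), Slit1 (1.82) and Unc5c (1.51) were among the migration genes that rose. Forebrain genes had a median of 1.41 with 8 of 13 higher and 1 lower, the same numbers as adjusted over the list alone (camera adjusted p = 0.028), including Hesx1 (-2.29). For the forebrain list adjusted p = 0.623 with an estimated correlation. Its call ended without step 5 control replicate 2 (1.02, camera adjusted p = 0.0872) or step 5 enriched replicate 1 (camera adjusted p = 0.0586). Lists that camera did not place apart had medians of 0.53 for the Notch pathway (adjusted p = 0.0621, 7 of 17 rose), -0.62 for endothelium (adjusted p = 0.0971), 0.35 for mesenchyme (adjusted p = 0.405) and 0.43 for cholesterol (adjusted p = 0.241). They were 0.69 for midbrain and hindbrain (adjusted p = 0.138), -0.18 for Hox genes (adjusted p = 0.229), 0.38 for glutamatergic genes (adjusted p = 0.46) and 0.24 for motor and cholinergic genes (adjusted p = 0.147). Notch genes passed camera without step 4 control replicate 2 (adjusted p = 0.0494) or step 5 enriched replicate 1 (adjusted p = 0.0387), and endothelial genes did, narrowly, without step 5 enriched replicate 3.

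**Figure D2:**
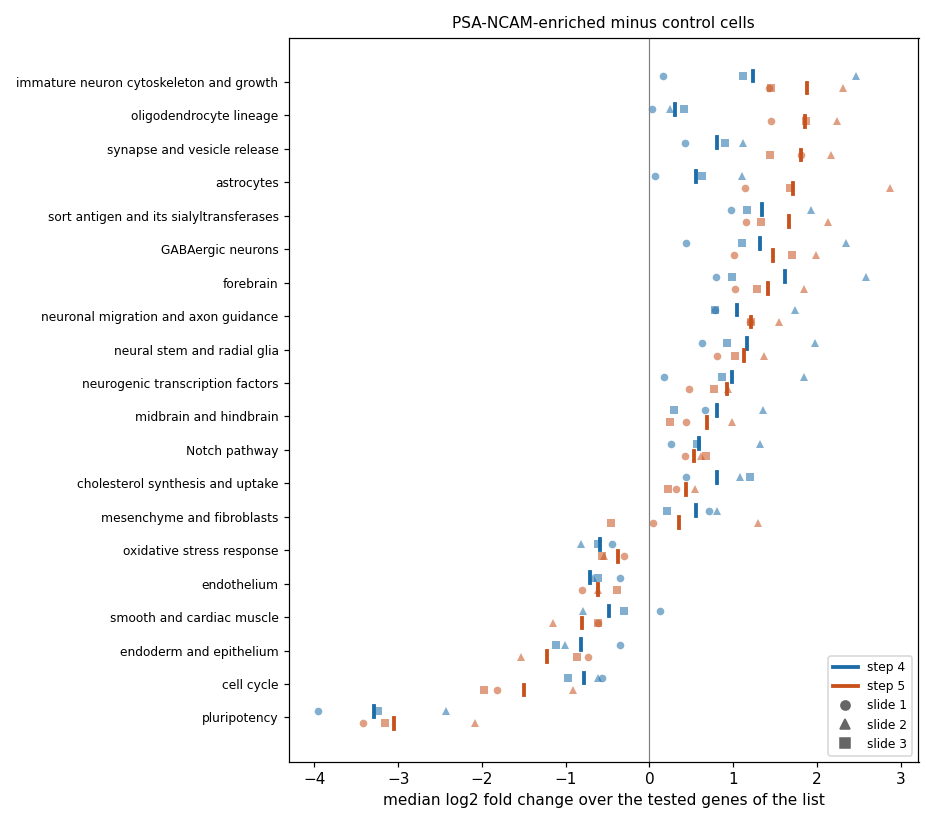
Median log2 difference between PSA-NCAM-enriched and control cells of the gene lists that camera placed apart at step 4 or step 5, with a bar for the estimate from all arrays and a point for each slide. Pluripotency genes lay at -3.29 and -3.05 and synaptic genes at 0.81 and 1.81 at steps 4 and 5, and each of these lists had the same sign on all 3 slides.

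The effects of enrichment at both steps were close to each other across genes, which are not independent replicates (r = 0.88, rho = 0.86, slope 1.04). In all, 2580 genes rose at both steps where 677.6 would be expected from the separate counts, 3055 fell at both where 727.7 would be expected, and 18 changed in opposite directions. Both comparisons share the same mESC reference and the same slides but no sample array. Deviations of same-numbered arrays from their group means correlated between the steps, at 0.463 to 0.747 in control and 0.341 to 0.413 in enriched cells. The expected numbers leave this out, since they treat the comparisons as independent.

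The third comparison asked which genes changed from step 4 to step 5 in PSA-NCAM-enriched cells. Between these steps bFGF was withdrawn, ascorbic acid at 200 µM was added and 7 days of differentiation passed. The design does not separate these. Of the oligodendrocyte lineage 10 of 15 genes rose and of the astrocyte genes 7 of 16, while 20 of 32 cell cycle genes, 7 of 18 cholesterol genes and 3 of 26 neurogenic transcription factors fell. Camera placed these 5 lists apart, but with an estimated correlation none passed (adjusted p = 0.175 with an estimated correlation for the lowest and 0.478 for the highest). Gfap rose 50.6-fold (log2 5.66, SE 1.05, n = 3 per group, adjusted p = 0.0132), with 5.76, 5.37 and 5.85 on slides 1, 2 and 3. Apoe rose 28.5-fold (log2 4.84, SE 0.39, adjusted p = 0.000365) and Mag 24.2-fold (log2 4.6, SE 0.51, adjusted p = 0.00176). Mki67 fell by 1.18 on the log2 scale (SE 0.24, adjusted p = 0.0181, 3 of 3 slides), a 2.26-fold difference. The neuronal markers Dcx (0.12, adjusted p = 0.955), Map2 (0.25, adjusted p = 0.881), Tubb3 (0.07, adjusted p = 0.976) and Ncam1 (0.22, adjusted p = 0.813) did not pass the test.

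By limma, 1433 genes (6.4% of those tested) changed between the steps in enriched cells, with 883 higher and 550 lower, and 502 and 140 of them changed at least 2-fold. With slide as a block the numbers were 1459 higher and 981 lower, 2440 in all, of which 1412 were shared. Beside Gfap, Apoe and Mag the largest rises were those of Bcas1 (47.1-fold, adjusted p = 0.00228), the matrix protein gene Mgp (33.6-fold, adjusted p = 0.0155), the water channel gene Aqp4 (29-fold, adjusted p = 0.0113), Cldn11 (26.9-fold) and Padi2 (25.7-fold). The largest falls were those of Fgfbp3 (12.3-fold, adjusted p = 0.00839), the embryonic myosin gene Myh3 (11.1-fold), Hmga2 (7.09-fold, adjusted p = 0.0283) and Fgf15 (6.91-fold). They were followed by Ano1 (5.37-fold), the FGF antagonist gene Il17rd (4.55-fold), the prolactin family gene Prl4a1 (4.46-fold) and Mfng (4.43-fold). All 16 were alike in sign on 3 of 3 slides, and Prl4a1 did not pass under 15 of 26 alternatives and Hmga2 under 9 of 27. Nes had a log2 change of -1.47 (SE 0.39, adjusted p = 0.0506, 0.00166 with slide as a block). Pou5f1 (0.41), Sox2 (-0.21) and Pax6 (-0.45) did not pass. Without 1 array the count was 445 (step 4 enriched replicate 2), 910 (step 4 enriched replicate 3), 789 (step 5 enriched replicate 2) or 610 (step 5 enriched replicate 3).

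Camera placed 7 lists higher and 5 lower from step 4 to step 5 in enriched cells, 0 with an estimated correlation, while fry called 5. Of the oligodendrocyte lineage 10 of 15 genes rose, or 13 adjusted over the list alone, with a median of 2.04 (camera adjusted p = 3.59e-14, slide medians 2.29, 1.15 and 2.0). Here adjusted p = 0.175 with an estimated correlation. Cnp rose 17-fold, Ugt8a 9.08-fold, Sox10 5.71-fold and Mobp 4.13-fold. Of the astrocyte genes 7 of 16 rose, or 10 adjusted over the list alone, with a median of 1.91 (camera adjusted p = 9.72e-09), including S100b (11.3-fold) and Gjb6 (8.48-fold). Cell cycle genes had a median of -0.91, with 20 of 32 lower and 30 adjusted over the list alone (camera adjusted p = 1.12e-21), and both lists had adjusted p = 0.298 with an estimated correlation. Ccna2 fell by 1.27 (SE 0.15), Birc5 by 1.35 (SE 0.17), Cenpe by 1.39 (SE 0.18) and Kif11 by 1.01 (SE 0.12). Synaptic genes had a median of 0.7 with 3 of 37 higher, or 7 adjusted over the list alone (camera adjusted p = 2.74e-07), and adjusted p = 0.506 with an estimated correlation. The 3 genes were Vamp2 (1.14), the glutamate receptor gene Grin1 (0.98) and Cplx1 (1.67), the last not past the test under 12 of 27 alternatives. Without step 4 enriched replicate 1 the synaptic median was 0.40.

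Neurogenic transcription factors had a median of -0.69 from step 4 to step 5 in enriched cells, with 3 of 26 lower, or 8 adjusted over the list alone (camera adjusted p = 1.21e-06). Here adjusted p = 0.478 with an estimated correlation. The 3 genes were Hes6 (-1.79, SE 0.32), Neurog2 (-1.4, SE 0.25) and Insm1 (-1.69, SE 0.43), the last not past the test under 16 of 27 alternatives. Cholesterol genes had a median of -0.92 with 7 of 18 lower, or 11 adjusted over the list alone (camera adjusted p = 2.51e-11, slide medians -0.15, -0.99 and -1.71). Notch pathway genes had a median of -0.48 with 1 of 17 lower, or 5 adjusted over the list alone (camera adjusted p = 0.0382), and the cholesterol and Notch lists both had adjusted p = 0.473 with an estimated correlation. Stard4 fell by 1.8 (SE 0.25) and Lss by 1.7. Genes of FGF and MAPK feedback had a median of -0.68 with 2 of 15 lower, also 2 adjusted over the list alone (camera adjusted p = 0.0154), with adjusted p = 0.567 with an estimated correlation. These were Il17rd (-2.19, SE 0.43) and Etv4 (-1.71, SE 0.44), the latter not past the test under 18 of 27 alternatives. Mesenchymal genes had a median of 0.63 with 2 of 26 higher, or 4 adjusted over the list alone (camera adjusted p = 0.000184), and adjusted p = 0.523 with an estimated correlation. The 2 genes were Thy1 (1.85) and Fap (2.86), the last not past the test under 9 of 27 alternatives. Radial glia genes (-0.4, camera adjusted p = 0.0733, 0.0464 with slide as a block) and pluripotency genes (0.28, camera adjusted p = 0.0678, 0.0407 with the block) passed with the block only. Both had adjusted p = 0.744 with an estimated correlation. Forebrain genes had a median of -0.27 (camera adjusted p = 0.0763), while Otx2 fell by 1.26, Lhx5 by 1.96 and Six6 by 1.59, the last not past the test under 18 of 26 alternatives. The medians with an array left out use only genes without a missing value. On those genes the medians from all arrays were -0.38 for the Notch pathway and -0.63 for FGF and MAPK feedback. The Notch call ended without step 4 enriched replicate 2 (-0.21, camera adjusted p = 0.0756), step 5 control replicate 2 (camera adjusted p = 0.0574), step 5 enriched replicate 1 (-0.21, camera adjusted p = 0.116) or 2 (camera adjusted p = 0.0759), and its median was -0.23 without step 5 enriched replicate 3. That of FGF and MAPK feedback ended without step 4 enriched replicate 1 (-0.33, camera adjusted p = 0.0809), step 5 enriched replicate 2 (camera adjusted p = 0.0759) or 3 (camera adjusted p = 0.0528), and its median was -0.98 without step 5 enriched replicate 1. Leaving out step 4 enriched replicate 1 moved the medians of neurogenic factors to -1.09 and of mesenchyme to 1.09, and leaving out step 4 enriched replicate 3 that of cholesterol to -0.61. Radial glia genes passed camera without step 4 enriched replicate 1 (adjusted p = 0.0126) or step 5 enriched replicate 3 (adjusted p = 0.00748). Pluripotency genes did so without step 4 enriched replicate 2 (0.63, adjusted p = 8.3e-05) or step 5 enriched replicate 3 (adjusted p = 0.00103), and forebrain genes without step 4 control replicate 2 (adjusted p = 0.043) or step 4 enriched replicate 1 (adjusted p = 0.0126).

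The fourth comparison asked the same of the control cells, where 0 genes changed from step 4 to step 5 by limma (smallest adjusted p = 0.147). At an unadjusted p under 0.05 there were 1917 genes, and with slide as a block 1 gene was higher. The main fit does not pair the arrays of a slide, and the block takes 1 slide effect for all 4 groups. Pairing the control arrays of a slide on their own was not tested. The changes in control cells had an SD over genes of 0.328 on the log2 scale, against 0.504 in enriched cells, and across genes, which are not independent replicates, both sets of changes correlated at r = 0.59. Gfap had a log2 difference of 3.73 (SE 1.05, adjusted p = 0.288, with 4.82, 1.01 and 5.37 on slides 1, 2 and 3) and Aqp4 of 2.33. The collagen genes Col1a1 and Col3a1 had differences of 2.5 (SE 0.61, adjusted p = 0.221) and 1.58 (SE 0.35, adjusted p = 0.176). Hes5 lay at -2.63 (SE 0.92, adjusted p = 0.412, with -2.52, -2.55 and -2.8 on slides 1, 2 and 3). Hes6 lay at -1.62 (SE 0.32, adjusted p = 0.147), and all 6 genes were alike in sign on 3 of 3 slides. Dcx had a difference of -1.08 and Pou5f1 of -0.02. Without step 5 control replicate 2 the count was 408, without step 4 control replicate 1 it was 58, and without the whole of slide 2 it was 81. Without step 5 control replicate 2, Gfap rose by 5.27 (adjusted p = 0.00171), Col3a1 by 1.97 (adjusted p = 0.0101) and Col1a1 by 3.12 (adjusted p = 0.0244).

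**Figure D3:**
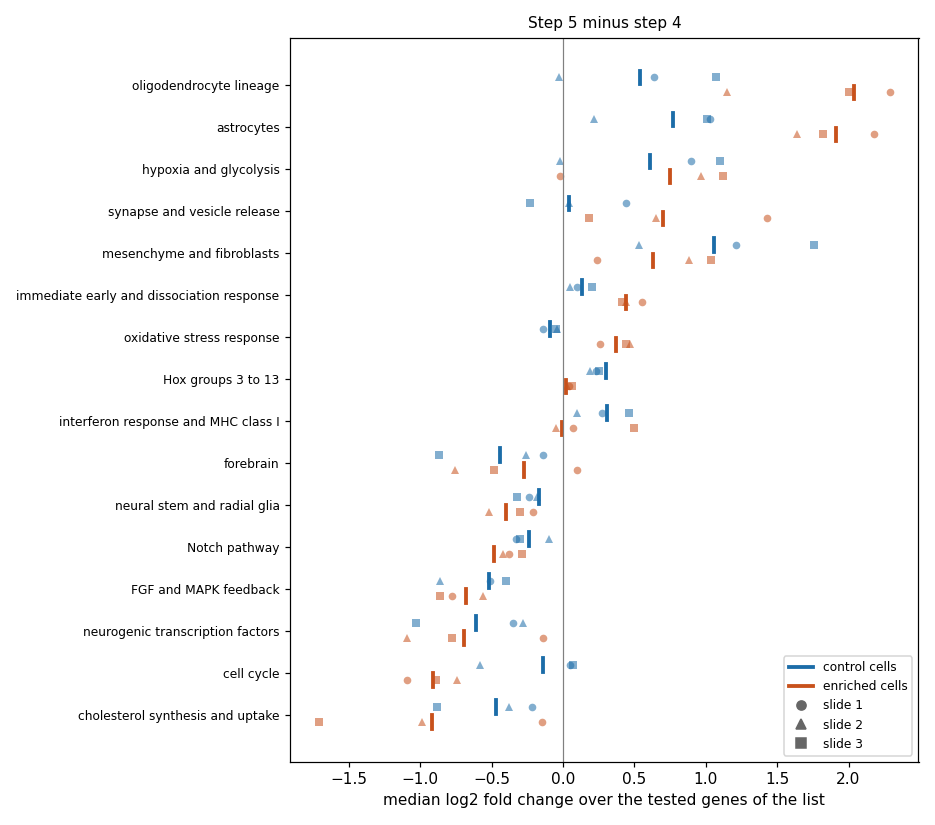
Median log2 difference between step 5 and step 4 of the gene lists that camera placed apart in control or enriched cells, with a bar for the estimate from all arrays and a point for each slide. The oligodendrocyte lineage lay at 0.54 in control cells and 2.04 in enriched cells, and cell cycle genes at -0.14 and -0.91.

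Camera placed 6 lists higher and 7 lower from step 4 to step 5 in control cells, 0 with an estimated correlation, while fry called 0. Mesenchymal genes had a median of 1.06 (camera adjusted p = 1.78e-12, slide medians 1.21, 0.53 and 1.76), with 14 of 26 higher adjusted over the list alone and adjusted p = 0.384 with an estimated correlation. Hox genes had a median of 0.3 (camera adjusted p = 6.82e-05), with 3 of 15 higher adjusted over the list alone. Notch pathway genes had a median of -0.24 (camera adjusted p = 0.00196) with 2 of 17 lower adjusted over the list alone, and the Hox and Notch lists both had adjusted p = 0.384 with an estimated correlation. Astrocyte genes had a median of 0.77 (camera adjusted p = 0.000838) and the oligodendrocyte lineage one of 0.54 (camera adjusted p = 0.000595, slide medians 0.64, -0.03 and 1.07). Both had adjusted p = 0.53 with an estimated correlation. Cholesterol genes had one of -0.47 (camera adjusted p = 1.39e-07), neurogenic transcription factors one of -0.61 (camera adjusted p = 4.22e-07), forebrain genes one of -0.44 (camera adjusted p = 0.00196) and FGF and MAPK feedback genes one of -0.52 (camera adjusted p = 0.00196). For these lists adjusted p = 0.53 with an estimated correlation. Adjusted over the list alone, 3 of the neurogenic and 1 of the forebrain genes were lower and 0 of the genes in the other 4 of these lists changed. Radial glia genes had a median of -0.17 (camera adjusted p = 0.0105) and cell cycle genes of -0.14 (camera adjusted p = 0.000838, slide medians 0.05, -0.58 and 0.07), with 0 of either past limma adjusted over the list alone. For both, adjusted p = 0.661 with an estimated correlation. Leaving out step 5 control replicate 2 ended the calls of cell cycle (0.07, camera adjusted p = 0.943), radial glia (-0.05, camera adjusted p = 0.785), forebrain (-0.14, camera adjusted p = 0.265) and FGF and MAPK feedback genes (camera adjusted p = 0.0968), and the astrocyte median was 1.28. The radial glia call ended also without step 4 control replicate 1 (camera adjusted p = 0.103) or 3 (camera adjusted p = 0.416), that of forebrain without step 4 control replicate 3 (camera adjusted p = 0.134) and that of FGF and MAPK feedback without step 4 control replicate 1 (camera adjusted p = 0.0703). Leaving out step 4 control replicate 2 gave medians of 0.45 for astrocytes, -0.84 for forebrain and -0.36 for radial glia. Leaving out step 4 control replicate 3 gave -0.40 for neurogenic factors, and step 5 control replicate 1 gave -0.26 for the cell cycle. Leaving out step 5 control replicate 3 gave 0.40 for astrocytes, 0.33 for the oligodendrocyte lineage, -0.27 for the cell cycle and -0.31 for radial glia. In all, 9 further lists passed camera with some array left out.

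The fifth comparison asked whether the effect of enrichment differed between step 4 and step 5. By limma it did so for 0 genes (smallest adjusted p = 0.0545), with 1574 at an unadjusted p under 0.05 and 0 with slide as a block. Without 1 array the count was 16 (step 5 control replicate 2), 6 (step 5 control replicate 3), 1 (step 5 enriched replicate 1) or 1 (step 5 enriched replicate 3). Ugt8a had the value 2.85 (SE 0.36, adjusted p = 0.0545), Mag 3.4 (SE 0.72, adjusted p = 0.286), Gjb6 2.9 (SE 0.62, adjusted p = 0.289) and Cnp 2.85 (SE 0.66, adjusted p = 0.305). Ccna2 lay at -0.93 (SE 0.21, adjusted p = 0.297), and all 5 genes were of the same sign on 3 of 3 slides. Ugt8a passed under 6 of 26 alternatives, among them without step 5 control replicate 2 (2.56, adjusted p = 0.0173) and without step 5 control replicate 3 (3.14, adjusted p = 0.0109). Genes such as Dcx (1.2) and Map2 (0.98), which passed the enrichment test at step 5 and not at step 4, were therefore not shown to differ between the steps. The same quantity is the difference between the step changes of enriched and control cells, and it was not shown for Gfap either (1.93, adjusted p = 0.904), which passed the step test in enriched and not in control cells. Camera placed 6 lists higher and 3 lower, 0 with an estimated correlation, and fry called 0. With slide as a block the number was 10, with the list of the sort antigen added (median 0.82, camera adjusted p = 0.0523, 0.0452 with the block). That list had adjusted p = 0.683 with an estimated correlation, and 0 of 5 genes passed limma adjusted over the list alone. It also passed camera with any of 5 single arrays left out, lowest without step 4 control replicate 2 (adjusted p = 0.00439). With this list included, 10 lists not called from all arrays passed camera with some array left out. The oligodendrocyte lineage had a median of 1.52 (camera adjusted p = 4.04e-14, 10 of 15 higher adjusted over the list alone). That list had adjusted p = 0.177 with an estimated correlation. Cell cycle genes had a median of -0.78 (camera adjusted p = 5.02e-21, 16 of 32 lower adjusted over the list alone) and adjusted p = 0.436 with an estimated correlation.

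The last comparison set each group against the mESC the cultures came from. Pluripotency genes lay closer to the mESC level in control cells than in enriched cells, and Fabp7 and Col1a1 lay above it in all 4 groups. Pou5f1 lay at -0.67 in step 4 control cells (SE 0.34, adjusted p = 0.145) and -0.69 in step 5 control cells (adjusted p = 0.123), against -4.45 and -4.04 in enriched cells. Its SD between arrays was 0.04 and 0.18 in these control groups and 0.82 and 1.02 in the enriched groups. The SE pools the spread of all 4 groups, so these p-values do not measure the spread of the control arrays. The counts of genes that follow rest on the same kind of pooled spread. Of 27 pluripotency genes, 16 and 14 were lower than in mESC in control cells of steps 4 and 5 (medians -0.93 and -0.88), and 27 in enriched cells of both steps (medians -4.72 and -4.02). Lefty1 and Lefty2 were lower in step 4 control cells by larger amounts, at -4.34 and -4.42. By limma, 8716 of 22450 genes differed from mESC in step 4 control cells (38.8%), 15013 in step 4 enriched cells (66.9%), 10017 in step 5 control cells (44.6%) and 16029 in step 5 enriched cells (71.4%). Without step 4 control replicate 3 the first of these counts was 5768.

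Fabp7, a marker of radial glia, lay at 5.8 and 6.94 in control and enriched cells of step 4 and at 5.42 and 6.55 in those of step 5. Col1a1 lay at 4.66, 5.68, 7.16 and 7.42, and 21, 22, 23 and 23 of the 26 mesenchymal genes were higher than in mESC in the same order of groups. Nes lay at 1.91, 3.09, 1.32 and 1.62, and Sox2, which mESC share with neural stem cells, at -1.47, -1.38, -1.62 and -1.59. Gfap lay at -0.06 (adjusted p = 0.961) and 0.67 (adjusted p = 0.448) at step 4 and at 3.67 and 6.33 at step 5. Of 15 genes of the oligodendrocyte lineage, 1 and 3 were higher than in mESC at step 4 in control and enriched cells, and 6 and 14 at step 5. In the same order 3 and 2 were lower at step 4, and 3 and 0 at step 5. Of 32 cell cycle genes, 13 and 29 were lower at step 4 and 17 and 32 at step 5, in the same order. These tests leave out the spread of the mESC themselves, and without a dye swap a dye effect of a probe cannot be separated from a difference. Centring each array on its median in place of loess moved the median log2 ratio of all genes to 0.299 and 0.372 in control and enriched cells of step 4 and to 0.3 and 0.416 in those of step 5, against 0.034, 0.032, 0.046 and 0.049.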

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

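Among the tests of this part, the splits of the samples and the bounds for the count without slide 2 were set before their results were seen. Leaving out whole slides was itself added after the data had been seen. The tests of mESC-like cells, of RNA mixing, of compression, of the size of the change in control cells and of the neurons, mESC share and scan of slide 2, and the look at all lists on slide 2 and at the make-up of the splits, were chosen only after the results were seen.

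The effect of enrichment differed between step 4 and step 5 for 9 lists by camera on the difference of the effects (10 with slide as a block, the list of the sort antigen added), in each case without a single gene past the limma test over all genes. The oligodendrocyte lineage (median difference 1.52), cell cycle genes (-0.78), astrocyte genes (1.17) and synaptic genes (0.64) had the lowest camera p among those that concern cell types, and their adjusted p with an estimated correlation was 0.177, 0.436, 0.436 and 0.683. The genes of the immature neuronal cytoskeleton had a difference of 0.59 (adjusted p = 0.92 with an estimated correlation). Cholesterol genes had one of -0.34 and immediate early genes one of 0.31, both with adjusted p = 0.683 with an estimated correlation. Hox genes had one of -0.19 and oxidative stress genes one of 0.45, both with adjusted p = 0.436 with an estimated correlation. The call of the cytoskeleton list ended without step 4 control replicate 3 (0.16, camera adjusted p = 0.451), step 4 enriched replicate 1 (0.15, camera adjusted p = 0.843), step 5 control replicate 2 (0.19, camera adjusted p = 0.385) or step 5 enriched replicate 1 (camera adjusted p = 0.051). That of immediate early genes ended with any of 5 arrays left out, with the highest camera adjusted p of 0.145 without step 4 control replicate 2. The astrocyte median was 0.45 without step 5 control replicate 2, the synaptic one 0.26 without step 4 control replicate 3 and that of cholesterol -0.07 without step 4 enriched replicate 3. Hox genes had a median of -0.3 without step 4 enriched replicate 3, and oxidative stress genes one of 0.26 without step 5 enriched replicate 1. With a real count of 0, all 100 of 100 splits of the arrays within each step reach it whatever the data, so the splits decide nothing about chance here. The highest other gave 2991. In that split 2 enriched arrays kept their label at step 4 and 0 at step 5, so the enrichment effect itself enters the difference. Only 3 splits called any gene, and in each of them the number of enriched arrays that kept their label differed by 2 between the steps. Other splits of that kind called 0 genes, and the reason for this was not tested. Among the 21 splits that part as many same-numbered pairs the highest was 24.

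Pluripotency genes lay nearer the mESC level on control arrays than on enriched arrays. Compression of the ratios on control arrays is argued against for the scanner's own log ratios. The lowest slope of the spike-in controls that its software gave on a control array was 0.914. Ratios after normexp and loess were not set against the spike-ins. With the scanner's log ratio the enrichment medians of pluripotency genes were -3.43 and -3.35 at steps 4 and 5. After loess they were -3.29 and -3.05. Of 241 genes bright in mESC and at least 8-fold lower in enriched cells, the median ratio was -1.1 on control arrays, and a share of mESC-like cells kept in the unsorted cultures may give such values. Its first test set the SD over these genes on control arrays against that on enriched arrays and gave 1.28, past the bound written against it. The choice of genes by a low enriched value narrows the enriched SD, so the test is void and this explanation stays open. Unaltered mESC or their RNA mixed into the control samples are argued against as the whole cause, since they would hold every gene bright in mESC at or above their share. Of the 241 genes, 15.8% lay below the median by over 1 on the log2 scale and past a test against it, 38 genes in all, and 39, 30 and 41 without slides 1, 2 and 3. The SD over these genes was 2.07 times that of a gene between control arrays (2.06 to 3.11 with a slide left out). Of 370 genes not detected in mESC, 141 rose with enrichment at step 5 and 6 fell, with a median log2 change of 0.44. More rises than falls would go with mESC-like cells or mESC RNA in the control samples. Mixing as the whole cause would raise all of them by 1 amount, and their changes had an SD of 0.89 with a median SE of 0.25. The 1.6% that fell lies between the bounds of 0 and 5%, which by itself decides nothing. All bounds on mixing were set once the SD over the 241 genes was known. Cells like mESC in a changed state, or a smaller share of mESC beside other causes, are not excluded by this.

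No gene passed from step 4 to step 5 in control cells while 1433 did in enriched cells, although limma found 1917 genes at an unadjusted p under 0.05 in control cells and 1 with slide as a block. Whether the change was smaller in control cells stays open. A first test, on genes chosen in enriched cells, was void because that choice favours these cells. Over all genes, the part of the change shared between slides had an SD in control cells of 0.61 times that in enriched cells, between the bounds of 0.5 and 0.8, with 0.456, 0.839 and 0.521 for slides 1 and 2, 1 and 3, and 2 and 3. Nor can it be told apart whether the control arrays of slide 2 hide the change, since without slide 2 the count in control cells was 81 against 310 in enriched cells, a ratio of 0.26 that lies between the bounds set for it. A biological difference between sorted and unsorted cultures stays open as well, and pairing the control arrays of a slide on their own was not tested. The difference between the step changes was itself past the test for 0 genes by limma, with 1574 at an unadjusted p under 0.05.

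The control arrays of slide 2 stood apart from the other control arrays, with a mean gap in correlation of 0.148. The enriched arrays on the same slide had a gap of -0.028. Their log2 ratios had SDs of 1.16 to 1.38 against 0.68 to 0.81 on control arrays, so the same slide effect would lower their correlations less. At step 4 enriched replicate 1 also stood apart, at r = 0.897 with replicate 3 against 0.963 for replicates 2 and 3. The scan and software of slide 2 therefore stay open as a cause of the gap in correlation on the control arrays. A larger share of mESC-like cells in the slide 2 control cultures is argued against, since the median ratio of genes restricted to mESC differed by -0.01. Fewer neurons in those cultures remain possible: the neuronal list differed there by -0.95 on average, with -1.26 at step 4 and -0.64 at step 5, and the second value misses the bound set for it. Neurons were not all that differed. The list of endoderm and epithelium stood higher there by 1.72 at step 4 and 1.57 at step 5. That of muscle stood higher by 0.9 and 1.47, while astrocyte genes differed by -0.58 and -1.72. The muscle list differed on the enriched arrays of this slide by 0.09 and 0.13 and the astrocyte list by 0.03 and -0.04. For these 2 lists the values argue against an effect of the slide that is alike on all its arrays. On the enriched arrays of slide 2 pluripotency genes stood higher by 1.38 and 1.52, and on its control arrays they differed by 0.06 and -0.08. The endoderm list stood higher on these enriched arrays by 1.26 and 1.22. The cause of both was not tested, so a shared culture, the sort or the slide itself stays open for them. No other biological explanation was tested.

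For the enrichment effects and the step changes there are 10 splits of 6 arrays, too few for a share under 0.05. At step 4 the real split gave 6950 genes and the highest other 26, and 1 of 10 splits, the real one, reached the real count. At step 5 the real split gave 9027 and the highest other 0, again with 1 of 10 at the real count. In enriched cells the steps gave 1433 and the highest other 0, and in control cells 0 with 1 as the highest other. A real count of 0 is reached by all 10 of 10 splits whatever the data, so for control cells the splits decide nothing. In each of these comparisons 4 of 10 splits part as many same-numbered pairs as the real one, and the highest other among them gave 0.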

How the results depend on the processing

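Leaving out whole slides, the block with an estimated correlation and the lists with each array left out were tests chosen after the data had been seen; all other alternatives were set before. The counts of enriched against control cells stayed within 1.5 times the reported ones under every change of background correction, normalization, filter, probe choice and block, and moved only with arrays left out. The number of genes at step 4 ranged from 1982 to 7712 with arrays or slides left out (4746, 3018 and 1982 without slides 1, 2 and 3) and at step 5 from 4324 to 9171. Fewer samples lower the power, but some counts rose above the reported ones, and the effect of which array was left out was not separated from this. From step 4 to step 5 in control cells the count was 2 with the scanner's log ratio, 2 with the deposited table, 1 with the block and 0 to 408 with arrays left out. In enriched cells it was 2440 with the block, 939 with only the arrays compared and 50 to 1764 with arrays left out (273, 310 and 50 without slides 1, 2 and 3). The difference of the enrichment effects gave 7 genes without background subtraction, 1 with the scanner's log ratio, 1 with median centring, 8 with Cy5 alone, 1 with the deposited table, 8 with the mean over probes, 7 with an intensity trend and 0 to 16 with arrays left out, and 0 with the block. Against mESC the count of step 4 control cells ranged from 3945 to 9392 and that of step 5 control cells from 5279 to 10079, with 6094 from only the arrays compared; the enriched groups stayed within 1.5 times. For all results that moved, the cause was not tested. Of 568 results for named genes, 360 kept their side of the threshold under every alternative. Where the gene passed in either setting, 0 changed sign. In 85 further cases the sign changed with the gene past the test in neither setting. Over all alternatives there were 667 cases of a passing gene that no longer passed, and fewer of a gene that newly passed.

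Of the lists camera placed apart, 0 passed with an estimated correlation and 0 with that and the block, in each of the 5 comparisons. With each array left out in turn, 11 of 17, 10 of 14, 8 of 13, 9 of 12 and 7 of 9 lists kept their call throughout (step 4, step 5, control cells, enriched cells and the difference). Fry called 11 lists at step 4, 0 from step 4 to step 5 in control cells, 5 in enriched cells and 0 for the difference of the effects. Median centring moved the median difference of all genes to 0.133 at step 4 and 0.134 at step 5 from 0.011 and -0.009, and the share of genes called higher from 48.1 to 65% and from 50.2 to 66.1%. Changes are given relative to loess, and small medians of lists are not firm. Scaling the mean intensities to the same quantiles after loess left every ratio as it was. Signals near background limit the ratios: where 1 group is dim, the fold is not well set.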

Other observations

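Tests in this part use lists fixed before the data were examined, and no test of an explanation was run here. Genes of the oxidative stress response had a median log2 change of -0.59 in enriched against control cells at step 4 (camera adjusted p = 0.0236, 3 of 3 slides), and 6 of 12 fell, also 6 adjusted over the list alone. Here adjusted p = 0.616 with an estimated correlation, and the call ended without step 4 control replicate 1 (camera adjusted p = 0.0502) or step 4 enriched replicate 2 (camera adjusted p = 0.0538). The detoxification gene Nqo1 fell 5.81-fold (SE 0.35 on the log2 scale, adjusted p = 0.000863), Gsta4 2.74-fold (SE 0.21) and Gclm 2.61-fold (SE 0.19). At step 5 the list had a median of -0.38 with 3 of 12 higher and 5 lower (camera adjusted p = 0.46). From step 4 to step 5 in enriched cells it had one of 0.37 (camera adjusted p = 0.0159), with 1 gene higher, also 1 adjusted over the list alone. That change had adjusted p = 0.473 with an estimated correlation, and the gene, Srxn1 (1.57, SE 0.40), did not pass under 16 of 27 alternatives. The call ended without step 4 enriched replicate 2 (camera adjusted p = 0.0542) or 3 (camera adjusted p = 0.0562) or step 5 enriched replicate 1 (camera adjusted p = 0.0877), and the median was 0.58 without step 4 enriched replicate 1. Genes of the immediate early and dissociation response had a median of 0.44 between the steps in enriched cells (camera adjusted p = 0.00428), with 2 of 19 higher, or 5 higher and 1 lower adjusted over the list alone. Here adjusted p = 0.473 with an estimated correlation, and the 2 genes were Fos (2.81, SE 0.38) and Nr4a1 (1.82, SE 0.40). Hypoxia and glycolysis genes had a median of 0.75 there (camera adjusted p = 1.57e-05, slide medians -0.02, 0.97 and 1.12), with 2 of 21 higher, or 3 adjusted over the list alone. This list too had adjusted p = 0.473 with an estimated correlation, and Ndrg1 rose by 2.12 and Pfkp by 1.68. Its median was 0.48 without step 5 enriched replicate 3.

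In control cells the hypoxia list had a median of 0.61 between the steps (camera adjusted p = 6.82e-05, slide medians 0.9, -0.02 and 1.1), with adjusted p = 0.53 with an estimated correlation and medians of 0.37 and 0.30 without step 5 control replicates 1 and 3. Interferon and MHC class I genes had one of 0.31 in control cells (camera adjusted p = 0.000595, 1 of 18 higher adjusted over the list alone), with adjusted p = 0.548 with an estimated correlation. That call ended without step 4 control replicate 1 (camera adjusted p = 0.103), and the median was 0.48, 0.54 and 0.20 without step 4 control replicate 2, step 5 control replicate 1 and step 5 control replicate 3. In enriched cells that list had a median of -0.01, which changed sign between scalings of the arrays (camera adjusted p = 0.369), with 2 of 18 genes higher, of which Ifit3 rose by 1.31 (SE 0.26, adjusted p = 0.0162). At step 4 the hypoxia list had a median of 0.07, a mean of -0.16 and a camera direction below 0 (adjusted p = 0.501), so these differ in sign. Pdk1 fell by 1.87 and Slc2a3 by 1.49. For retinoid response genes the median was 0.1 between the steps in enriched cells (camera adjusted p = 0.482), where the receptor gene Rarb rose by 2.1 (SE 0.33, adjusted p = 0.00699). The dopaminergic list had a median of 0.14 (camera adjusted p = 0.192), where the retinoid enzyme gene Aldh1a1 rose by 3.71 (SE 0.44).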
